A study of Triticum aestivum with 48 samples.

How the data were processed

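Transcript levels were measured on the Affymetrix Wheat Genome Array in roots and shoots of 15 day old seedlings of 4 wheat genotypes, HD2967, K9107, K307 and Chotilarma (CL), supplied with 8 mM calcium nitrate (control) or 0.08 mM (stressed). Each of the 16 groups held 3 arrays, 48 in all, and the labels give 3 replicate numbers to each group. The tissue characteristic of CL stressed root array 1 reads shoot while its title and description read root. It was kept as root: the first principal component, with 53.1% of the variance within normalization sets, put all 24 root arrays, this one included, on one side and all 24 shoot arrays on the other.

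The deposited values are log2 signal intensities of 61290 probe sets, which the authors made with RMA, per the submitters' processing notes. Import into GeneSpring 14.5 and a Student's test at p of at most 0.1 per probe set followed, per the series description. The RMA version, its settings and which arrays were normalized together are not given in the sources used here. The array medians fell in 4 separate ranges of 12 arrays each, parted by gaps of over 0.1 and called normalization sets 1 to 4 here: 1.14 to 1.26, 4.33 to 4.47, 4.61 to 4.68 and 5.32 to 5.39. Set 1 held all 12 CL arrays and no others, so the CL scale and the CL genotype cannot be told apart. The other sets mixed HD2967, K9107 and K307. HD2967 shoot arrays of the 2 N supplies shared no set.

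Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided), 1 fit of 24 arrays per tissue, with Benjamini-Hochberg adjustment over 61179 probe sets and a threshold of 0.05. The 111 control probe sets were left out and 64 reporter probe sets were kept. The groups, contrasts, threshold and gene naming rule were fixed before the data were examined, with no term for the normalization set. The set was added to every fit as a fixed term after the array medians were seen, before any difference was tested, so the reported fit is not the one first fixed. Counts from the fit first fixed stand beside the reported ones. The set term lowered the median residual SD from 0.435 to 0.227 in roots and from 0.458 to 0.247 in shoots, and left 14 residual degrees of freedom. With no set term, the median difference over all probe sets was 0.20 in HD2967 roots, -0.28 in K307 roots, and 0.40, -0.27 and -0.30 in HD2967, K9107 and K307 shoots. With it, these medians lay between -0.06 and 0.02. The CL values were compressed at the low end: probe sets with a set 3 level of 0 to 4 had a CL median of 0.757, and those of 4 to 6 a CL median of 1.33. CL log2 differences were therefore not read as ordinary folds. The average N response is the mean of the 4 genotypes' responses, so each average mixes the 2 scales. The F-test of genotype at control N covered only HD2967, K9107 and K307. Tests of genotype by N that include CL compare responses on 2 scales.

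The annotation pairs 1273 probe sets with exactly 1 gene (771 genes), 0 with several, and leaves 60017 unnamed here. Of these genes, 770 were found by gene ID in the reference table of assembly IWGSC CS RefSeq v2.1, and 102 genes with 200 probe sets carried an informative name. A gene was read from its probe set of highest mean in the tissue. The rule named, per tissue average, up to 12 rises and 12 falls with 1 sign in all 4 genotypes, per genotype up to 3 rises and 3 falls with no overlap of set-adjusted values, per interaction or genotype test the 6 smallest p, and per list up to 4 members that passed. Where none passed, the 3 smallest p were named as not passed. As fixed, the overlap was to be read on the values themselves, and the set adjustment was added with the set term. Gene lists fixed before the data were examined matched at most 3 probe sets each, too few for a test of at least 5, so 10 lists were rebuilt from the named genes after the annotation and array medians were seen and before any response was seen. Lists with at least 5 probe sets (9 of the 10) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation.

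Whether replicate numbers pair arrays was checked by the correlation of residuals between same-numbered control and stressed arrays. In CL shoots all 3 correlations passed 0.1 (0.115 to 0.228), so the numbers were taken to pair those arrays, and a fit with a replicate block within CL is given beside that result. The pairing comes from these values alone, not from the labels. In other groups such correlations ran from -0.522 to 0.556, so values of this size are weak evidence of pairing. The fits were tested on simulated data with known changes over 61179 probe sets: 99 of 100 changes of 1 log2 unit were recovered for the root average and 92 for the shoot average, 28 for HD2967 shoots and 46 for CL shoots. The simulated values had independent normal residuals and the fitted set offsets. This recovery thus does not test the set term, the CL scale or a structure among the arrays. Alternatives covered the set term, replicate block, each array left out in turn, only the brighter probe sets (above the median), 2 other scalings, 48 arrays in 1 fit, only the 6 arrays compared, array weights, a trended robust prior, the methods' own test, a log2 difference of at least 1, 1 probe set per gene, the list correlation, and fits without CL or HD2967. The number of arrays limits the precision, and p-values measure only the spread between arrays and nothing beyond the plants grown here. Figures were drawn with matplotlib 3.10.9.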

Results

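The study asked how seedlings of 4 wheat genotypes respond to chronically low nitrogen. Groups of 3 arrays, control and stressed, were compared in roots and in shoots, for HD2967, K9107, K307 and CL. Each of the 16 groups held 3 arrays of 61290 probe sets, and the medians of the arrays ran from 1.14 to 5.39 in 4 separate normalization sets. Differences are stressed minus control on the log2 scale, ± standard error, with 3 arrays per N supply.

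**Figure D1:**
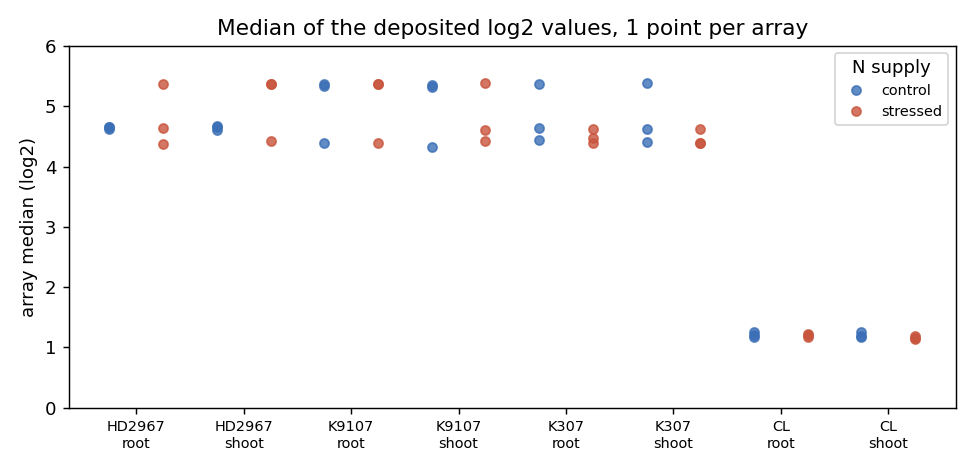
Median of the deposited log2 values (y axis) for each of the 48 arrays, 1 point per array, by genotype and tissue (x axis) and N supply (colour). The 12 CL arrays lie between 1.14 and 1.26, below the other 36 arrays.

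In roots, averaged over the 4 genotypes, TaALMT1, an aluminium-activated malate transporter, rose by 0.84 ± 0.24 (adjusted p = 0.0419) and UBC1, a ubiquitin-conjugating enzyme, rose by 0.47 ± 0.07 (adjusted p = 0.000383). The alpha-tubulin gene TUBA fell by 0.24 ± 0.06 (adjusted p = 0.0332). UBC1 and TUBA had 1 sign in all 4 genotypes. TaALMT1 lay at 2.23 ± 0.48 in K307, 0.90 ± 0.46 in CL, 0.24 ± 0.46 in K9107 and 0.00 ± 0.53 in HD2967. The Rubisco large subunit gene rbcl, higher by 0.74 ± 0.22 (adjusted p = 0.0489), differed in sign between genotypes, and so did Glc1, which fell by 0.48 ± 0.13 (adjusted p = 0.0311). Of the 102 named genes 6 passed, and 7 when adjusted over the list alone. Among called probe sets with no informative name and 1 sign in all 4 genotypes, the 2 largest rises were 3.93 ± 0.35 and 3.08 ± 0.28, both paired with 1 gene, and the 2 largest falls were -3.28 ± 0.23 and -2.89 ± 0.29. In all, 4018 probe sets (2132 higher, 1886 lower) passed, and 742 did with no set term. Of them, 1475 had a positive and 1384 a negative estimate in every genotype. Adjusted p with no set term was 0.313 for TaALMT1, 0.105 for UBC1, 0.769 for TUBA, 0.143 for rbcl and 0.272 for Glc1. TaALMT1 lost its call in 15 of the 24 fits with 1 array left out (adjusted p up to 0.135). TUBA lost its call in 12 of the 24 fits with 1 array left out (adjusted p up to 0.116). rbcl lost its call in 17 of the 24 fits with 1 array left out (adjusted p up to 0.203). Glc1 lost its call in 10 of the 24 fits with 1 array left out (adjusted p up to 0.0881). With HD2967 out of the average, Glc1 lay at -0.15 (adjusted p = 0.718), rbcl at 0.41 (adjusted p = 0.466) and TUBA at -0.26 (adjusted p = 0.0501). Without the 12 CL arrays, TaALMT1 lay at 0.82 (adjusted p = 0.0828), rbcl at 0.74 (adjusted p = 0.0894) and TUBA at -0.20 (adjusted p = 0.0509). The count was 2563 without K307 root control 3 and 2645 without HD2967 root stressed 3, and 6668 without the 12 CL arrays.

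Of the 9 gene lists tested in roots, tubulins passed, with a median of -0.27 over 10 probe sets and TUBA called lower (adjusted p = 0.0462). That call was lost with an estimated correlation (adjusted p = 0.694). Core histones did not pass: the histone genes wcH2B-8, wcH2A-3 and wcH2A-2 lay at -0.23 ± 0.16, 0.13 ± 0.11 and -0.06 ± 0.17. Photosynthesis genes had 1 of 36 probe sets higher, from rbcl, and defence genes 1 of 15 lower, from Glc1. No probe set passed among LEA and cold-induced proteins (EM -0.17 ± 0.10, LEA1 -0.41 ± 0.29, Rab15 -0.17 ± 0.13) or fructan and starch genes (6-FEH -0.21 ± 0.10, Wx-A1 -0.21 ± 0.10, AGA.1 -0.14 ± 0.07). The same held for peroxidases and related enzymes (PER1 -0.35 ± 0.13, lgul 0.18 ± 0.09, Trx-M 0.36 ± 0.18) and translation genes (RPS29 -0.48 ± 0.18, eIF-2-beta 0.18 ± 0.07, eIF4E-1 0.21 ± 0.09). Grain proteins had none passing either (Gli-8 -0.39 ± 0.12, Gli-D2-16 -0.33 ± 0.11, Serpin-Z2A -0.51 ± 0.19). The gibberellin 20-oxidases, too few to test as a list, lay at -0.11 ± 0.09 (GA20ox1d), 0.12 ± 0.13 (GA20ox1b) and 0.03 ± 0.07 (GA20ox1a). The smallest adjusted p among these unpassed genes was 0.0692, for Gli-8. The shoot markers for root samples, PsbO and PsbP, had a median of -0.09 over 3 probe sets.

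In HD2967 roots, FKBP70, an FK506-binding protein, fell by 1.68 ± 0.24 (adjusted p = 0.000947), Glc1 changed by -1.50 ± 0.29 (adjusted p = 0.00695) and GAPN, a glyceraldehyde-3-phosphate dehydrogenase, fell by 1.29 ± 0.34 (adjusted p = 0.0427). Hmgb3, a high-mobility group protein, rose by 1.08 ± 0.27 (adjusted p = 0.0354). In all, 2058 probe sets (929 higher, 1129 lower) passed, and 418 with no set term. Quantile normalization again gave 255 higher and 658 lower. Adjusted p with no set term was 0.00743 for FKBP70, 0.0879 for Glc1, 0.391 for GAPN and 0.223 for Hmgb3. Glc1 lost its call without HD2967 root stressed 3 (adjusted p = 0.101). GAPN lost its call in 5 of the 6 fits with 1 array left out (adjusted p up to 0.130). Hmgb3 lost its call whichever of the 6 arrays was left out (adjusted p up to 0.176). The count was 421 without HD2967 root stressed 3, 1002 without HD2967 root control 3, 1105 without HD2967 root control 2 and 1335 without HD2967 root stressed 2. Stressed arrays 1 and 2 share no set with a control, so their part rests on set offsets estimated with the other genotypes. In a fit with no other genotype the set term leaves stressed 3 alone against the 3 controls, and limma called 0, with 8429 at unadjusted p under 0.05.

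K307 roots had TaALMT1 higher by 2.23 ± 0.48 (adjusted p = 0.0180), and the protease inhibitor Serpin-Z2A fell by 1.47 ± 0.37 (adjusted p = 0.0489). No named gene passed in K9107 roots, where UBC1 lay at 0.55 ± 0.14 (adjusted p = 0.0616), petC at 1.19 ± 0.46 and RPS29 at -0.83 ± 0.34. In K307, 1219 probe sets (760 higher, 459 lower) passed, and in K9107 555 probe sets (342 higher, 213 lower). With no set term, 167 and 89 passed, and adjusted p in K307 was 0.249 for TaALMT1 and 0.130 for Serpin-Z2A. Fits with no other genotype called 118 in K307, where control 2 shares no set with a stressed array and drops out, and 1603 in K9107. TaALMT1 lost its call without K307 root control 3 (adjusted p = 0.216), without K307 root stressed 1 (adjusted p = 0.0761) and without K307 root stressed 3 (adjusted p = 0.0530). Serpin-Z2A lost its call whichever of the 6 arrays was left out (adjusted p up to 0.410). The K307 count was 263 without K307 root control 3 and 647 without K307 root stressed 1. The K9107 count was 215 without K9107 root control 1, 266 without K9107 root control 2, 271 without K9107 root stressed 1, 335 without K9107 root stressed 3 and 336 without K9107 root control 3.

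In CL roots the zinc finger gene WZF1 rose by 1.90 ± 0.36 (adjusted p = 0.00928), FKBP70 by 0.99 ± 0.21 (adjusted p = 0.0170) and UBC1 by 0.59 ± 0.14 (adjusted p = 0.0279). The histone gene wcH2B-8 fell by 1.86 ± 0.30 (adjusted p = 0.00315), and 7 of 18 core histone probe sets were lower, with a list median of -1.13 (adjusted p = 1.71e-12). The list call was lost with an estimated correlation (adjusted p = 0.296). In all, 1246 probe sets (770 higher, 476 lower) passed, and 109 with no set term. Quantile normalization again gave 2311 higher and 2201 lower. Adjusted p with no set term was 0.0905 for WZF1, 0.290 for FKBP70, 0.995 for UBC1 and 0.0515 for wcH2B-8. WZF1 lost its call without CL root control 2 (adjusted p = 0.0579). FKBP70 lost its call without CL root control 2 (adjusted p = 0.0811). UBC1 lost its call without CL root stressed 1 (adjusted p = 0.0710), without CL root stressed 3 (adjusted p = 0.0666) and without CL root control 2 (adjusted p = 0.126). The count was 632 without CL root control 2 and 3121 without CL root stressed 2, and 3 from the 6 arrays alone.

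**Figure D2:**
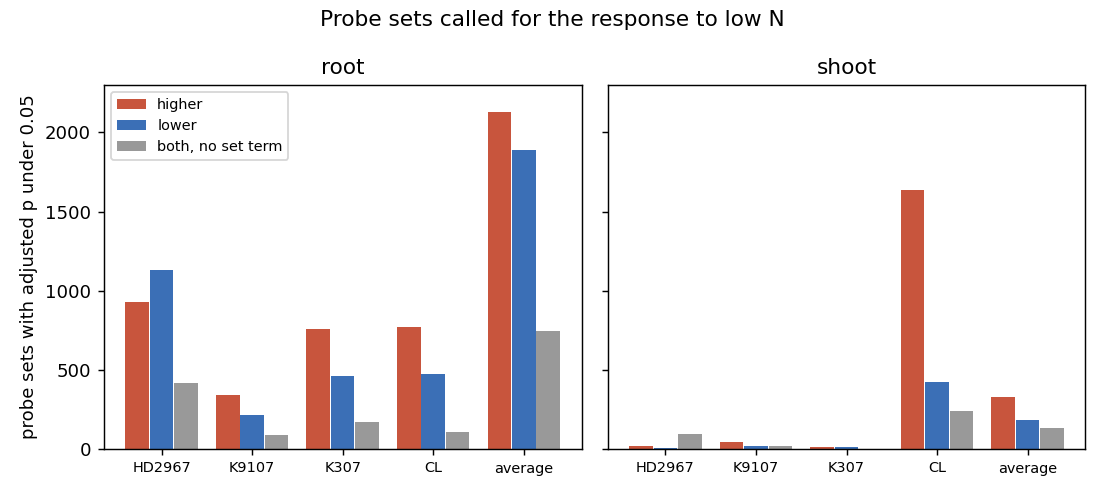
Number of probe sets with adjusted p under 0.05 (y axis) for each genotype and the average (x axis) in roots and shoots. Bars show those higher and lower in stressed samples, and both together with no set term, which in CL shoots were 1635, 422 and 237.

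Root responses differed between genotypes for FKBP70, WZF1 and wcH2B-8. FKBP70 lay at -1.68 ± 0.24 in HD2967, -0.02 ± 0.21 in K9107, 0.36 ± 0.22 in K307 and 0.99 ± 0.21 in CL (adjusted p = 0.00134). WZF1 lay at -1.35 ± 0.42, 0.04 ± 0.36, -0.82 ± 0.38 and 1.90 ± 0.36 (adjusted p = 0.0123), and wcH2B-8 at 0.06 ± 0.35, 0.46 ± 0.30, 0.43 ± 0.31 and -1.86 ± 0.30 (adjusted p = 0.0159). For TaALMT1 the difference did not pass (adjusted p = 0.238). In all, 896 probe sets passed, and 137 with no set term, where adjusted p was 0.0178 for FKBP70, 0.0860 for WZF1 and 0.138 for wcH2B-8. Without the 12 CL arrays, adjusted p was 0.197 for WZF1 and 0.811 for wcH2B-8. wcH2B-8 lost its call without CL root control 3 (adjusted p = 0.0504). The count was 523 without HD2967 root stressed 3, 533 without HD2967 root control 2, 566 without HD2967 root stressed 2, 579 without K307 root control 1, 587 without K307 root control 3 and 2090 without CL root stressed 2. Between K9107 and K307, 181 probe sets were higher and 80 lower in both, against 4.25 and 1.60 for independent lists, and a difference passed for 1. Between HD2967 and CL, 31 were higher and 65 lower in both, against 11.7 and 8.78, while 116 were called in opposite directions and a difference passed for 978. The correlation of these responses across all probe sets was 0.0508. No value for independent lists was worked out for the opposite directions. Lists from 1 fit, here and in shoots, share the residual variance of each probe set, so they are not fully independent. Called in each of the 4 genotypes were 15 probe sets as higher and 15 as lower.

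In shoots, averaged over genotypes, TaALMT1 rose by 2.88 ± 0.32 (adjusted p = 0.000257), with 4.56 ± 0.64 in K307, 4.12 ± 0.66 in K9107, 2.54 ± 0.62 in CL and 0.31 ± 0.84 in HD2967. CL controls lay at 0.83 ± 0.10 (mean ± SD), at the compressed low end, so the size there is uncertain. The TaALMT1 responses were not shown to differ between genotypes (adjusted p = 0.311). The catalase gene CAT1 fell by 0.66 ± 0.14 (adjusted p = 0.0417) and the xylanase inhibitor gene XIP-I fell by 0.62 ± 0.12 (adjusted p = 0.0179), both with negative estimates in all 4 genotypes, although CAT1 passed in no genotype by itself and in K307 lay at -0.42 within set 2 and 0.45 within set 3. Of the 102 named genes 3 passed, and 4 when adjusted over the list alone. Among called probe sets with no informative name and 1 sign in all 4 genotypes, the 2 largest rises were 3.25 ± 0.27 and 3.10 ± 0.27, and the 2 largest falls were -2.02 ± 0.16 and -1.97 ± 0.15. Both rises came from probe sets with the same base identifier, so they may not be separate results. The largest fall ran from -4.56 in HD2967, whose N supplies share no set, to -0.18 in CL. In all, 515 probe sets (330 higher, 185 lower) passed, and 134 with no set term. Quantile normalization again gave 228 higher and 203 lower. Adjusted p with no set term was 0.000183 for TaALMT1, 0.212 for CAT1 and 0.259 for XIP-I. CAT1 lost its call in 18 of the 24 fits with 1 array left out (adjusted p up to 0.140). XIP-I lost its call without K9107 shoot stressed 3 (adjusted p = 0.0660) and without K307 shoot stressed 3 (adjusted p = 0.0685). The count was 218 without K9107 shoot stressed 3, 223 without K307 shoot control 1, 246 without K307 shoot stressed 3, 249 without K307 shoot control 2, 281 without HD2967 shoot control 2, 310 without K9107 shoot control 1, 315 without CL shoot stressed 2, 328 without K307 shoot stressed 2, 873 without CL shoot control 3 and 893 without HD2967 shoot control 1. Without the 12 CL arrays it was 203, with XIP-I at -0.28 (adjusted p = 0.486) and CAT1 at -0.63 (adjusted p = 0.281). With HD2967 out of the average CAT1 lay at -0.60 (adjusted p = 0.103).

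**Figure D3:**
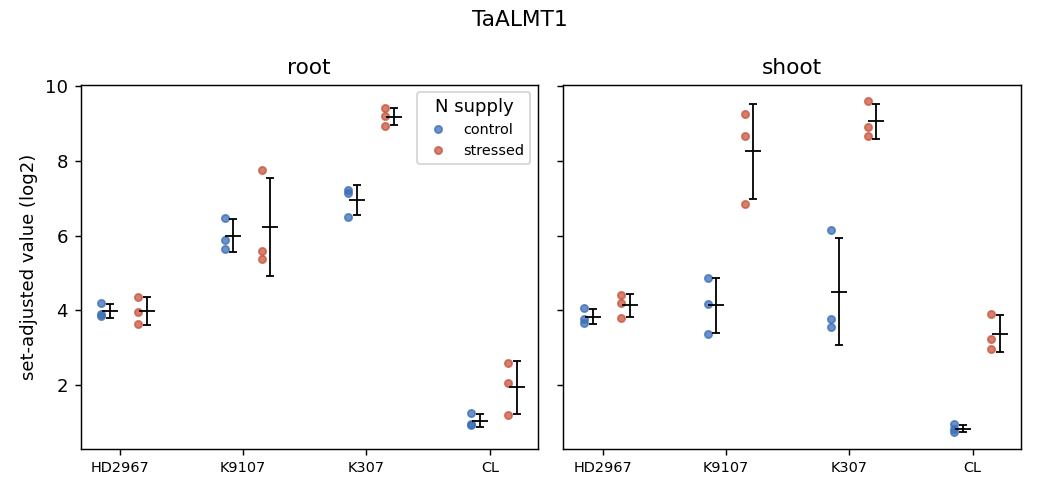
TaALMT1 in roots and shoots: set-adjusted log2 value (y axis) per array, 1 point each, by genotype (x axis) and N supply (colour), with mean and SD of 3 arrays. CL is on the scale of its own set. In stressed K9107 shoots the mean was 8.25 ± 1.27, against 4.13 ± 0.74 in controls.

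Of the 9 gene lists tested in shoots, 7 passed. Thionins and other defence genes had 3 of 15 probe sets lower, from XIP-I and the thionin gene THI1.3 (adjusted p = 0.000782, and 0.0149 as adjusted p with an estimated correlation). The other 6 calls were lost with an estimated correlation (adjusted p = 0.279 for each). The called defence members rested on different genotypes. Within sets, the brightest THI1.3 probe set lay at -2.48 and -2.27 in K307 and -0.44 in CL, but at 0.24 and 0.87 in K9107. Without the 12 CL arrays, XIP-I lay at -0.28 (limma adjusted p = 0.486). Core histones had a median of 1.16 with 17 of 18 probe sets above 0 (adjusted p = 6.91e-05) and tubulins a median of 0.85 (adjusted p = 0.000216), with no probe set passing by itself. These averages pool medians of opposite sign: histones at 3.61 in CL and 2.80 in K9107 but -0.65 in HD2967 and -1.47 in K307, tubulins at 2.64, 1.17, -0.36 and -0.68. Single arrays stood apart, HD2967 control 1 with a histone median of 11.71 against 6.99 and 6.84, and K307 control 3. Members lay at 1.21 ± 0.51 (wcH2A-3), 0.52 ± 0.23 (wcH2B-6), 1.23 ± 0.63 (wcH2B-8), 1.11 ± 0.32 (Tubb5), 0.50 ± 0.23 (tubb1) and 0.29 ± 0.16 (TUBA), the last at -0.00881 without the CL arrays. Photosynthesis genes had a median of -0.16 over 36 probe sets (adjusted p = 0.00322), with FBP at -0.52 ± 0.19, petC at -0.31 ± 0.13 and PRK at -0.41 ± 0.21, none passing. Fructan, sucrose and starch genes had 2 of 10 higher, both from the fructan exohydrolase gene 6-FEH (adjusted p = 0.0204), while 1-FEHw2 lay at 0.21 ± 0.13, AGA.1 at -0.13 ± 0.11 and AGP-S at 0.06 ± 0.11. Peroxidases and related enzymes had CAT1 lower (adjusted p = 0.0204). Grain proteins had a median of -0.13 (adjusted p = 0.00322), with no member passing: an alpha-amylase/trypsin inhibitor (ATI) lay at -0.17 ± 0.09, Gli-D2-1 at -0.15 ± 0.09 and LMW-D7 at -0.17 ± 0.10. Translation genes (TEF1 0.21 ± 0.08, eIF4E-1 0.24 ± 0.11, RPS29 -0.45 ± 0.21) and LEA proteins (LEA1 1.28 ± 0.76, COR410 -0.09 ± 0.09, Rab15 0.26 ± 0.48) did not pass. The gibberellin 20-oxidases lay at 0.32 ± 0.18 (GA20ox1a), 0.19 ± 0.19 (GA20ox1b) and -0.07 ± 0.35 (GA20ox1d).

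In CL shoots the histone genes wcH2B-8 and wcH2A-3 rose by 4.89 ± 1.21 (adjusted p = 0.0335) and 3.87 ± 0.97 (adjusted p = 0.0359), and the beta-tubulin gene Tubb5 by 3.50 ± 0.62 (adjusted p = 0.00572). In controls these lay at 1.66 ± 0.87, 1.05 ± 0.04 and 1.82 ± 0.99 (mean ± SD), near the CL array medians, at the compressed low end and not shown to be above background, so the sizes are uncertain. Over the lists, 4 of 18 histone and 7 of 10 tubulin probe sets were higher, with medians of 3.61 (adjusted p = 1.24e-08) and 2.64 (adjusted p = 7.25e-11). Both list calls were lost with an estimated correlation (adjusted p = 0.194 and 0.131). XIP-I fell by 1.66 ± 0.23 (adjusted p = 0.00123). ATI was called lower (adjusted p = 0.0417), but at 1.18 ± 0.47 its controls already lay near the array medians and were not shown to be above background, so no size is given. In all, 2057 probe sets (1635 higher, 422 lower) passed, 237 with no set term, and 3417 with a replicate block within CL. Quantile normalization again gave 3292 higher and 3487 lower. Adjusted p with no set term was 0.0985 for wcH2B-8, 0.102 for wcH2A-3, 0.0279 for Tubb5, 0.0386 for XIP-I and 0.862 for ATI. wcH2B-8 lost its call in 4 of the 6 fits with 1 array left out (adjusted p up to 0.125). wcH2A-3 lost its call in 5 of the 6 fits with 1 array left out (adjusted p up to 0.15). ATI lost its call in 4 of the 6 fits with 1 array left out (adjusted p up to 0.141). The count was 503 without CL shoot stressed 2, 943 without CL shoot stressed 1, 1349 without CL shoot control 1, 3351 without CL shoot control 2 and 4700 without CL shoot control 3, and 371 from the 6 arrays alone.

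**Figure D4:**
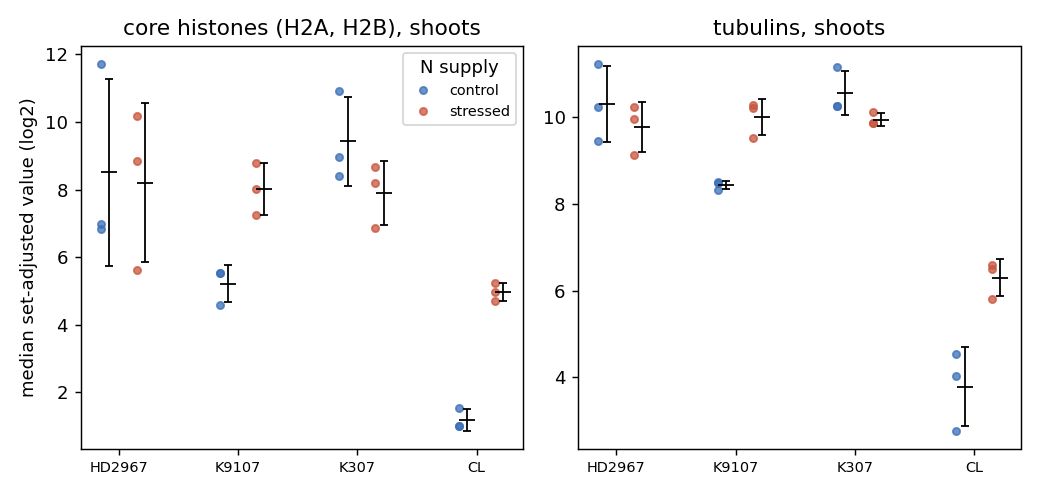
Median set-adjusted log2 value (y axis) of the core histone and the tubulin probe sets in each shoot array, 1 point each, by genotype (x axis) and N supply (colour), with mean and SD of 3 arrays. CL is on the scale of its own set. The median responses in CL were 3.61 and 2.64.

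TaALMT1 was the named gene that passed in K9107 shoots, higher by 4.12 ± 0.66 (adjusted p = 0.0223). In K307 shoots TaALMT1 rose by 4.56 ± 0.64 (adjusted p = 0.0160) and THI1.3 fell by 2.04 ± 0.30 (adjusted p = 0.0161). Histone and tubulin lists had medians of 2.80 and 1.17 in K9107 and -1.47 and -0.68 in K307, and each passed (adjusted p = 1.93e-10, 1.04e-07, 0.000828 and 0.00103). None of the 4 held with an estimated correlation (adjusted p = 0.165, 0.165, 0.537 and 0.533). No named gene passed in HD2967 shoots, where FKBP70 lay at -0.99 ± 0.25, Tubb4 at -1.03 ± 0.29 and RPS29 at -1.59 ± 0.54. The HD2967 differences rest on set offsets estimated from the other genotypes, since its 2 N supplies share no set. In K9107 64 probe sets (45 higher, 19 lower) passed, in K307 28 probe sets (14 higher, 14 lower) and in HD2967 22 probe sets (16 higher, 6 lower). With no set term these were 17, 2 and 91, and adjusted p was 0.0255 for TaALMT1 in K9107, 0.0483 in K307 and 0.0901 for THI1.3. Quantile normalization again gave 3 higher and 2 lower in HD2967. In K307, control 3 stood apart with a histone median of 10.92, against 8.40 and 8.96 in controls 1 and 2, and wcH2B-8 differed by -4.23 within set 3, which holds that control, and by -0.35 within set 2. TaALMT1 lost its call without K9107 shoot stressed 2 (adjusted p = 0.325), without K9107 shoot control 3 (adjusted p = 0.0570) and without K9107 shoot control 1 (adjusted p = 0.170). TaALMT1 lost its call without K307 shoot stressed 2 (adjusted p = 0.0766), without K307 shoot control 3 (adjusted p = 0.0952) and without K307 shoot stressed 3 (adjusted p = 0.0703). THI1.3 lost its call in 4 of the 6 fits with 1 array left out (adjusted p up to 0.213). The K9107 count was 6 without K9107 shoot stressed 1, 7 without K9107 shoot control 1, 8 without K9107 shoot stressed 2, 22 without K9107 shoot control 2 and 337 without K9107 shoot stressed 3. The K307 count was 4 without K307 shoot stressed 2 and 7 without K307 shoot control 1. The HD2967 count was 7 without HD2967 shoot control 2, 12 without HD2967 shoot stressed 2 and 14 without HD2967 shoot control 3. Fits with no other genotype gave 1052 in K9107, and limma called 0 in K307 with 4112 at unadjusted p under 0.05.

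No named gene passed the test of differing shoot responses over all probe sets, while 6 did when adjusted over the list alone. The smallest adjusted p were 0.0864 for THI1.3, 0.130 for FKBP70 and 0.160 for XIP-I. Over all probe sets 36 passed, and 1 with no set term. Without the 12 CL arrays limma called 0, with 4370 at unadjusted p under 0.05. The count was 11 without HD2967 shoot stressed 2, 12 without CL shoot stressed 2, 17 without K307 shoot stressed 2 or CL shoot stressed 1, 18 without K9107 shoot stressed 2 or HD2967 shoot control 2, 19 without K9107 shoot control 1, 21 without K9107 shoot stressed 1 or K307 shoot stressed 1, 59 without CL shoot stressed 3, 64 without K307 shoot control 3 or CL shoot control 2, 87 without HD2967 shoot stressed 1 and 263 without CL shoot control 3. Across all probe sets the responses of K9107 and CL had a correlation of 0.535, and those of HD2967 and K307 0.275. The other 4 pairs had negative correlations: -0.238 for HD2967 and K9107, where shared set offsets alone gave -0.208, -0.260 for K9107 and K307, -0.102 for HD2967 and CL, and -0.0974 for K307 and CL. Between K9107 and CL, 8 probe sets were higher and 3 lower in both, against 1.2 and 0.131 for independent lists.

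At control N, HD2967, K9107 and K307 differed in named genes of both tissues (set-adjusted mean ± SD, n = 3 arrays). HD2967 controls lie in set 3 alone and K9107 controls in sets 2 and 4 alone, so their differences rest wholly on set offsets estimated from other groups, and of the K307 controls only root control 1 and shoot control 3 share set 3. A part of the set layout in these differences stays open. In roots, the same HD2967 control arrays also enter the HD2967 N responses and the genotype by N test, so these results are not independent. FKBP70, Glc1 and Hmgb3 responded in HD2967 roots towards the control levels of K9107 and K307. A part of the HD2967 control arrays themselves thus stays open too. In roots FKBP70 lay at 11.86 ± 0.34 in HD2967, 9.95 ± 0.08 in K9107 and 9.84 ± 0.04 in K307 (limma adjusted p = 4.15e-05). In the same order, Hmgb3 lay at 9.95 ± 0.20, 11.56 ± 0.12 and 11.80 ± 0.35 (adjusted p = 0.000486), Glc1 at 10.12 ± 0.22, 8.27 ± 0.12 and 8.39 ± 0.15 (adjusted p = 0.00112) and TaALMT1 at 3.98 ± 0.18, 6.0 ± 0.43 and 6.95 ± 0.39 (adjusted p = 0.00323). Tubb5 lay at 9.47 ± 0.08, 10.49 ± 0.05 and 10.74 ± 0.11 (adjusted p = 0.00690) and the small heat shock gene hsp16.9A at 6.04 ± 1.94, 3.49 ± 0.07 and 3.42 ± 0.17 (adjusted p = 0.0285). In shoots the thionin genes THI1.3 and THI1.1 lay at 3.11 ± 0.22, 2.51 ± 0.15 and 7.12 ± 0.58 (adjusted p = 1.05e-08) and 4.09 ± 0.36, 3.55 ± 0.41 and 8.03 ± 0.50 (adjusted p = 5.34e-06). FKBP70 lay at 11.41 ± 0.33, 10.07 ± 0.08 and 9.45 ± 0.10 (adjusted p = 4.31e-05), RPS29 at 8.46 ± 0.59, 6.55 ± 0.66 and 5.78 ± 0.55 (adjusted p = 0.00445), Hmgb3 at 10.60 ± 0.53, 10.11 ± 0.45 and 11.97 ± 0.18 (adjusted p = 0.00683) and XTH, a xyloglucan endotransglucosylase, at 9.04 ± 1.49, 6.29 ± 0.35 and 9.46 ± 0.46 (adjusted p = 0.0113). Over all probe sets 5519 differed in roots and 4524 in shoots. With no set term 3437 and 2502 passed, and 61087 and 60980 where CL was in the test too. XTH was not called with no set term and no CL (adjusted p = 0.147). TaALMT1 lost its call without K307 root control 1 (adjusted p = 0.0976). Tubb5 lost its call without K307 root control 1 (adjusted p = 0.137). hsp16.9A lost its call without K307 root control 3 (adjusted p = 0.0510), without K307 root control 1 (adjusted p = 0.132) and without HD2967 root control 3 (adjusted p = 0.0644). XTH lost its call without K307 shoot control 2 (adjusted p = 0.0627) and without K9107 shoot control 1 (adjusted p = 0.0886). The root count was 3323 without K307 root control 1. The shoot count was 2330 without K9107 shoot control 1, 2612 without K307 shoot control 2 and 2875 without K307 shoot control 3.

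Responses differed between tissues for 6 named genes (8 when adjusted over the list alone), given as root response minus shoot response over 48 arrays. UBC1 lay at 0.51 ± 0.09 (adjusted p = 0.00164) and CAT1 at 0.96 ± 0.25 (adjusted p = 0.0426), the response being higher in roots. The mean CAT1 level was 3.86 in roots and 9.67 in shoots, so its root signal was dim and not shown to be above background. TaALMT1 lay at -2.01 ± 0.39 (adjusted p = 0.00333), Tubb5 at -1.34 ± 0.35 (adjusted p = 0.0384), TUBA at -0.62 ± 0.17 (adjusted p = 0.0497) and DMAS1, a deoxymugineic acid synthase of iron uptake, at -0.46 ± 0.12 (adjusted p = 0.0446), all with the response higher in shoots. In all, 996 probe sets (439 higher, 557 lower) passed, and 133 with no set term, where adjusted p was 0.257 for UBC1, 0.496 for CAT1, 0.0370 for TaALMT1, 0.212 for Tubb5, 0.488 for TUBA and 1.00 for DMAS1. CAT1 lost its call in 28 of the 48 fits with 1 array left out (adjusted p up to 0.0767). Tubb5 lost its call in 29 of the 48 fits with 1 array left out (adjusted p up to 0.0697). TUBA lost its call in 37 of the 48 fits with 1 array left out (adjusted p up to 0.0852). DMAS1 lost its call in 34 of the 48 fits with 1 array left out (adjusted p up to 0.0744). The count was 1906 without HD2967 shoot control 1. Without the 12 CL arrays the calls of 4 ended, with Tubb5 at -0.65 (adjusted p = 0.585), TUBA at -0.31 (adjusted p = 0.516), DMAS1 at -0.21 (adjusted p = 0.482) and CAT1 at 1.198 (adjusted p = 0.0694), so the first 3 rest largely on CL with its compressed scale. Of the probe sets called in the averages, 105 were higher and 38 lower in both tissues, against 11.5 and 5.70 for independent lists. In opposite directions, 13 were higher in roots and lower in shoots and 5 the reverse, against 6.45 and 10.2.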

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

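The tests chosen only after results were seen were those of a single array, the CL normalization, the spread between shoot arrays, the HD2967 set layout and the normalization set, and the expectations for relabelled arrays were written down after their counts were known.

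Responses differed between genotypes in roots for 896 probe sets. Relabelling N within genotypes gave at most 270, so 1 of 100 labellings reached the real count and chance can be excluded. Between 2 genotypes, a difference passed for 143 to 978 probe sets where HD2967 or CL was in the pair. For K9107 and K307 it passed for 1. The count thus rests largely on HD2967, with stressed arrays in sets that hold none of its controls, and on CL with its other scale. A part of the set layout and of the CL scale stays open. FKBP70 (adjusted p = 0.00134), WZF1 (0.0123) and wcH2B-8 (0.0159) were among the 896. Without the CL arrays, limma adjusted p was 0.00660 for FKBP70, 0.197 for WZF1 and 0.811 for wcH2B-8. With no set term 137 probe sets passed. The exclusion of chance thus holds for the count and not for these genes singly. In shoots responses differed for 36 probe sets. There 2 of 100 labellings, the real one included, gave as many, but the other one gave 114, several times the real count. With 0 called by limma without the CL arrays (4370 at unadjusted p under 0.05) and 1 with no set term, a structure among the arrays stays open for this count.

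Responses differed between tissues for 996 probe sets, and relabelled arrays gave at most 17 (1 of 100 labellings reached the real count), so chance can be excluded. The named genes, as root minus shoot response, were UBC1 at 0.51, TaALMT1 at -2.01, Tubb5 at -1.34, CAT1 at 0.96, DMAS1 at -0.46 and TUBA at -0.62. Without the 12 CL arrays Tubb5 lay at -0.65 (adjusted p = 0.585), DMAS1 at -0.21 (adjusted p = 0.482), TUBA at -0.31 (adjusted p = 0.516) and CAT1 at 1.198 (adjusted p = 0.0694). With no set term the differences of the named genes kept their sizes, but only TaALMT1 kept its call. Each set holds as many stressed and as many control arrays in roots as in shoots, so set offsets cancel in root minus shoot. The kept sizes were thus fixed by the layout and are no test of the set term. The exclusion of chance thus holds for the count and not for these genes singly.

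Among 25 control probe sets for wheat housekeeping genes, left out of the tests above, the one for glucose-6-phosphate dehydrogenase (AFFX-Ta_G-6-PDH_3_s_at) fell by 0.43 ± 0.11 in stressed roots on average (limma adjusted p = 0.0332 over these probe sets).

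The core histone and tubulin lists passed as higher in stressed CL shoots, with medians of 3.61 and 2.64 and 4 of 18 and 7 of 10 probe sets passing. Both list calls were lost with an estimated correlation (adjusted p = 0.194 and 0.131). The histone medians of the CL controls were 1.00, 1.55 and 1.01, near the array medians and not shown to be above background, so the size of the difference is uncertain. Left out in turn, no single CL array brought the medians below 3.43 and 1.84, and 2 other scalings gave at least 3.57 and 2.30. RNA quality was argued against as the whole cause, since with actin and gapdh 3' minus 5' differences as covariates the medians were 3.89 and 1.91. Histone medians varied about as much between arrays of 1 group elsewhere, with 11.71, 6.99 and 6.84 in HD2967 controls, 10.17, 8.83 and 5.61 in HD2967 stressed shoots and 10.92 in K307 control 3, and in K307 the response was -1.47. K9107 shoots moved as CL did, with histone medians of 8.01, 8.78 and 7.26 in stressed arrays against 4.59, 5.54 and 5.52 in controls. In HD2967, as in K307, the median response was negative. Differences in the share of dividing tissue between samples were not tested and stay open, as do the compressed CL scale and effects of N supply itself.

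More probe sets were called in roots than in shoots, 4018 against 515. Larger spread between shoot arrays stays open. Given the shoot standard errors of the same rank, 2131 root differences passed, and given the shoot errors of the same probe sets 2668 did, both above the shoot count, but given the root errors 2085 and 4158 shoot differences passed, the latter more than in roots. The set layout of the HD2967 shoot arrays was argued against, since without HD2967 the root count was 5.57 times the shoot count. Single responses did differ between tissues (996 probe sets, tissue by N), but that test does not show that roots respond in more genes, which stays open too.

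TaALMT1 was higher in stressed shoots of K9107, K307 and CL. The normalization set was argued against, since the 5 differences between arrays of the same set ran from 2.54 to 6.03. Root tissue in the shoot samples was argued against by probe sets with at least the root over shoot difference of TaALMT1 at control N, whose median shoot response was at most 0.22 and upper quartile at most 1.17. In CL that difference was 0.21, so 17190 probe sets entered and the test says less there. An effect of low N in the shoot is a hypothesis found and tested on the same arrays.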

How the results depend on the processing

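Alternatives chosen after the data were seen were the set term of the reported fits, the rebuilt lists, array medians subtracted with no set term, the fits without CL or without HD2967, the genotype tests with no set term and no CL, the differences within sets and the replicate block within CL. Counts that moved by over 1.5 times follow by alternative, and unless stated the cause was not tested. A remark in parentheses on an alternative, such as fewer arrays, describes it and was not tested as the cause. Every other count of an alternative fitted to the whole design stayed within 1.5 times.

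Counts are from limma, and from camera for lists. With no set term, as first fixed, the counts were 418 for HD2967 root, 89 for K9107 root, 167 for K307 root, 109 for CL root, 91 for HD2967 shoot, 17 for K9107 shoot, 2 for K307 shoot, 237 for CL shoot, 742 for root average, 137 for genotype by N in root, 61087 for genotype at control N in root, 134 for shoot average, 1 for genotype by N in shoot, 60980 for genotype at control N in shoot and 133 for tissue by N. Over the brighter probe sets, above the median (fewer tested), the counts were 5 for HD2967 shoot, 15 for K307 shoot, 0 for lists in root (2 at unadjusted p under 0.05) and 4 for lists in shoot. After quantile normalization again, the counts were 913 for HD2967 root, 245 for K9107 root, 475 for K307 root, 4512 for CL root, 5 for HD2967 shoot, 6 for K9107 shoot, 6 for K307 shoot, 6779 for CL shoot, 2881 for genotype at control N in root, 61 for genotype by N in shoot and 2172 for genotype at control N in shoot. With array medians subtracted, the counts were 14 for HD2967 shoot and 0 for lists in root (1 at unadjusted p under 0.05). With 48 arrays in 1 fit, the counts were 1.2e+02 for HD2967 shoot (87 higher, 36 lower), 831 for K9107 shoot, 84 for K307 shoot, 3925 for CL shoot, 1948 for shoot average, 859 for genotype by N in shoot and 8359 for genotype at control N in shoot. From fits of only the 6 arrays (fewer arrays), the counts were 0 for HD2967 root (8429 at unadjusted p under 0.05), 1603 for K9107 root, 118 for K307 root, 3 for CL root, 1052 for K9107 shoot, 0 for K307 shoot (4112 at unadjusted p under 0.05) and 371 for CL shoot. With array weights, the counts were 3877 for HD2967 root, 4805 for K9107 root, 2744 for CL root, 45 for HD2967 shoot, 1792 for K9107 shoot, 217 for K307 shoot, 7714 for root average, 3360 for genotype by N in root, 9432 for genotype at control N in root, 2776 for shoot average, 397 for genotype by N in shoot, 10370 for genotype at control N in shoot and 5273 for tissue by N. With a trended robust prior, the count was 20 for genotype by N in shoot. With 1 probe set per gene (fewer tested), the counts were 53 for HD2967 root, 32 for K9107 root, 37 for K307 root, 73 for CL root, 2 for HD2967 shoot, 12 for K9107 shoot, 5 for K307 shoot, 146 for CL shoot, 106 for root average, 57 for genotype by N in root, 114 for genotype at control N in root, 0 for lists in root (0 at unadjusted p under 0.05), 73 for shoot average, 13 for genotype by N in shoot, 106 for genotype at control N in shoot, 4 for lists in shoot and 69 for tissue by N. With an estimated list correlation, the counts were 0 for lists in root (0 at unadjusted p under 0.05) and 1 for lists in shoot. With array medians subtracted and no set term, the counts were 334 for K9107 root, 723 for CL root, 153 for HD2967 shoot, 17 for K307 shoot, 1349 for CL shoot, 47980 for genotype at control N in root, 0 for lists in root (1 at unadjusted p under 0.05), 46887 for genotype at control N in shoot and 584 for tissue by N. Without the 12 CL arrays, the counts were 4258 for HD2967 root, 1071 for K9107 root, 2987 for K307 root, 5 for HD2967 shoot, 34 for K9107 shoot, 10 for K307 shoot, 6668 for root average, 8653 for genotype at control N in root, 0 for lists in root (2 at unadjusted p under 0.05), 203 for shoot average, 0 for genotype by N in shoot (4370 at unadjusted p under 0.05) and 3 for lists in shoot. Without HD2967 in the average, the count was 2527 for root average. With no set term and CL kept out of the genotype test, the counts were 3437 for genotype at control N in root and 2502 for genotype at control N in shoot. For lists with 1 probe set per gene, the counts were 0 for lists in root and 2 for lists in shoot. At a log2 difference of at least 1 (stricter), the counts were 1277 for HD2967 root, 691 for K307 root, 670 for CL root, 1296 for CL shoot, 366 for root average, 135 for shoot average and 418 for tissue by N. Unless CL is said to be kept out, the fits with no set term had CL in the test of genotype at control N, while the reported test leaves CL out. With CL kept out, array medians subtracted and no set term gave 6769 in root and 4876 in shoot, within 1.5 times the reported counts. Most of the rise thus came with the CL arrays, whose scale and genotype cannot be told apart. In the fits of only the 6 arrays, an array whose set holds no array of the other N supply is absorbed by the set term. HD2967 root is thus compared as 1 stressed array against 3 controls, its spread coming from the controls alone, and 1 array drops out in K307 root, K307 shoot and K9107 shoot.

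The methods' own Student's test per probe set, at unadjusted p of at most 0.1, passed 8290 for HD2967 root, 1924 for K9107 root, 6172 for K307 root, 6422 for CL root, 11194 for HD2967 shoot, 1565 for K9107 shoot, 3665 for K307 shoot and 10320 for CL shoot. After adjustment it passed 0 in each at 0.05, and 0 at 0.1 except 3 for CL shoot, while 4341 for HD2967 root, 1046 for K9107 root, 3060 for K307 root, 3082 for CL root, 5404 for HD2967 shoot, 587 for K9107 shoot, 1619 for K307 shoot and 5724 for CL shoot had an unadjusted p under 0.05.

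With a replicate block, the counts were 3 for HD2967 shoot, 31 for K9107 shoot, 0 for lists in root (1 at unadjusted p under 0.05) and 23 for genotype by N in shoot. With a replicate block within CL, the count was 3417 for CL shoot. With the block over all genotypes, named calls were lost at adjusted p = 0.0659 (GAPN, HD2967 root), 0.0650 (Serpin-Z2A, K307 root), 0.0547 (TaALMT1, root average), 0.0541 (TUBA, root average), 0.0508 (TaALMT1, K9107 shoot) and 0.05004 (Glc1, root average). The block changed no other count by over 1.5 times. Outside CL shoots, correlations of same-numbered arrays ran from -0.522 to 0.556, no genotype and tissue had all 3 pairs over 0.1, and the numbers were not taken as pairing.

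Within single sets, with 1 to 3 arrays per N supply, limma called 61 in set 1 for CL root, 941 in set 1 for CL shoot, 0 (2790 at unadjusted p under 0.05) in set 2 and 18 in set 4 for K9107 root, 55 in set 2 and 9 in set 3 for K307 root, 1379 in set 2 and 6 in set 4 for K9107 shoot, 11 in set 2 and 9 in set 3 for K307 shoot and 21 in set 3 for HD2967 root. An arm held 1 array everywhere except in CL and in set 4 for K9107 root, and a lone array gives no spread of its own, so it was assumed to vary like the other arrays of its set. In set 2 the spread came from the stressed K307 arrays alone, so the K9107 counts there rest on another genotype.

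Named genes that lost their calls are given with the adjusted p. Calls lost under quantile normalization again were 0.275 (GAPN) in HD2967 root, 0.0568 (TaALMT1) and 0.354 (Serpin-Z2A) in K307 root, 0.109 (UBC1) in CL root, 0.0789 (hsp16.9A) in genotype at control N in root, 0.0568 (Tubb5), 0.104 (CAT1), 0.154 (DMAS1) and 0.0722 (TUBA) in tissue by N, 0.0625 (TaALMT1) in K9107 shoot, 1.00 (THI1.3) in K307 shoot, 0.0592 (CAT1) in shoot average and 0.0829 (rbcl) in root average. Lost with 48 arrays in 1 fit were 0.193 (Hmgb3) in HD2967 root, 0.451 (wcH2B-8) in CL root, 0.0721 (TaALMT1) and 0.197 (TUBA) in root average, 0.784 (wcH2B-8) in genotype by N in root, 0.660 (Tubb5) and 0.0621 (hsp16.9A) in genotype at control N in root, 0.132 (ATI) in CL shoot and 0.0534 (CAT1) in shoot average. Calls lost in fits of only the 6 arrays were 0.178 (Hmgb3), 0.141 (FKBP70), 0.111 (Glc1) and 0.234 (GAPN) in HD2967 root, 0.0886 (Serpin-Z2A) in K307 root, 0.518 (WZF1), 0.568 (FKBP70), 0.509 (UBC1) and 0.378 (wcH2B-8) in CL root, 0.116 (TaALMT1) in K9107 shoot, 0.373 (TaALMT1) and 0.183 (THI1.3) in K307 shoot and 0.0581 (Tubb5), 0.0798 (XIP-I) and 0.426 (ATI) in CL shoot. Lost with array weights were 0.0830 (TaALMT1) and 0.109 (Serpin-Z2A) in K307 root, 0.0607 (WZF1) in CL root and 0.117 (ATI) in CL shoot. Calls lost with a trended robust prior were 0.0618 (UBC1) in CL root, 0.0690 (TUBA) in root average and 0.0650 (DMAS1) and 0.0508 (TUBA) in tissue by N. Lost with array medians subtracted were 0.0540 (Serpin-Z2A) in K307 root, 0.0507 (TUBA) in root average, 0.0687 (DMAS1) in tissue by N and 0.0560 (CAT1) in shoot average. Calls lost with array medians subtracted and no set term were 0.262 (Serpin-Z2A) in K307 root, 0.0722 (FKBP70) and 0.233 (UBC1) in CL root, 0.325 (TUBA) and 0.0506 (rbcl) in root average, 0.155 (UBC1), 0.0578 (Tubb5), 0.0518 (CAT1), 0.170 (DMAS1) and 0.196 (TUBA) in tissue by N, 0.125 (THI1.3) in K307 shoot and 0.0608 (wcH2B-8), 0.0581 (wcH2A-3) and 0.0736 (ATI) in CL shoot. Lost without the 12 CL arrays were 0.0828 (TaALMT1), 0.0509 (TUBA) and 0.0894 (rbcl) in root average, 0.197 (WZF1) and 0.811 (wcH2B-8) in genotype by N in root, 0.0517 (hsp16.9A) in genotype at control N in root, 0.585 (Tubb5), 0.0694 (CAT1), 0.482 (DMAS1) and 0.516 (TUBA) in tissue by N, 0.0811 (TaALMT1) in K9107 shoot, 0.0991 (TaALMT1) and 0.0527 (THI1.3) in K307 shoot and 0.281 (CAT1) and 0.486 (XIP-I) in shoot average. Calls lost without HD2967 in the average were 0.0501 (TUBA), 0.466 (rbcl) and 0.718 (Glc1) in root average and 0.103 (CAT1) in shoot average. Lost with no set term and CL kept out of the genotype test were 0.147 (XTH) in genotype at control N in shoot. Calls lost with array medians subtracted, no set term and CL kept out of it were 0.0660 (XTH) in genotype at control N in shoot.

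With each array left out in turn, an arm with 2 arrays left, counts ran from 7 to 18 for HD2967 shoot, 218 to 893 for shoot average, 11 to 263 for genotype by N in shoot, 757 to 1906 for tissue by N, 421 to 2373 for HD2967 root, 2563 to 5157 for root average, 523 to 2090 for genotype by N in root, 0 to 1 for lists in root, 215 to 452 for K9107 root, 6 to 337 for K9107 shoot, 2330 to 5148 for genotype at control N in shoot, 4 to 37 for K307 shoot, 3323 to 5191 for genotype at control N in root, 263 to 1259 for K307 root, 503 to 4700 for CL shoot and 632 to 3121 for CL root. The count of root lists was 0 without K9107 root stressed 1 or K9107 root control 3 or K307 root control 3 or K307 root stressed 1 or K9107 root stressed 3 or K9107 root control 2 or K307 root control 1 or HD2967 root stressed 3 or HD2967 root control 2 or HD2967 root control 3 or CL root stressed 1 or CL root control 1 or CL root control 3. Average responses of genes that had not passed ran from -0.0225 to 0.66 for Rab15 in shoots, -0.00965 to 0.12 for AGP-S in shoots, -0.25 to 0.15 for GA20ox1d in shoots, -0.19 to 0.0601 for wcH2A-2 in roots and -0.0171 to 0.0808 for GA20ox1a in roots, changing sign.

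Averages that changed sign, none of which had passed, were wcH2A-2 in roots at 0.0481 (no set term), 0.0900 (array medians subtracted, no set term), 0.00811 (without the 12 CL arrays) and 0.0601 (without HD2967 root stressed 3), GA20ox1d in shoots at 0.0172 (no set term), 0.00560 (all 48 arrays in 1 fit), 0.0140 (array weights), 0.0603 (array medians subtracted, no set term), 0.0854 (without the 12 CL arrays), 0.21 (without HD2967 in the average), 0.0828 (without HD2967 shoot stressed 1), 0.0510 (without K9107 shoot control 3), 0.15 (without K9107 shoot stressed 3), 0.11 (without HD2967 shoot control 1) and 0.0322 (without CL shoot control 1), AGP-S in shoots at -0.00323 (replicate block), -0.0264 (array weights), -0.0125 (without HD2967 in the average) and -0.00965 (without K9107 shoot control 2), GA20ox1b in shoots at -0.12 (quantile normalization again), wcH2A-3 in roots at -0.0149 (all 48 arrays in 1 fit), GA20ox1b in roots at -0.00818 (array weights), COR410 in shoots at 0.0144 (array medians subtracted, no set term) and 0.0544 (without HD2967 in the average), wcH2B-8 in roots at 0.32 (without the 12 CL arrays), TUBA in shoots at -0.00881 (without the 12 CL arrays), GA20ox1a in roots at -0.0171 (without K307 root control 2) and Rab15 in shoots at -0.0225 (without K9107 shoot stressed 3). The fits of only the 6 arrays could not be made for HD2967 shoots, whose N supplies share no set. Signal over background was not given, so what dim probe sets limit was not analysed here.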

Other observations

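The expectations for relabelled arrays were written down after the counts were known, and 6-FEH was singled out after its values were seen. In shoots, 2 probe sets of the fructan exohydrolase gene 6-FEH were higher on average, by 0.90 ± 0.18 and 1.03 ± 0.22 (limma adjusted p = 0.0219 and 0.0355). Neither was the brightest probe set of the gene. In CL shoots Hmgb3 lay higher by 1.80 ± 0.35, DMAS1 by 0.93 ± 0.17, the elongation factor gene TEF1 by 0.68 ± 0.16 and TCTP by 0.47 ± 0.10 (adjusted p = 0.00960, 0.00838, 0.0254 and 0.0203), beyond those the naming rule took.

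Counts were set against relabelled arrays. For the root average, 4018 were called and at most 771 in the other labellings, with 1 of 100 reaching the real count, so chance can be excluded. For the shoot average, 515 were called and at most 9 in the other labellings, with 1 of 100 reaching the real count, so chance can be excluded. For genotype at control N in root, 5519 were called and at most 3327 in the other labellings, with 1 of 100 reaching the real count, so chance can be excluded. For genotype at control N in shoot, 4524 were called and at most 2180 in the other labellings, with 1 of 100 reaching the real count, so chance can be excluded. For lists in shoot, 7 were called and at most 7 in the other labellings, with 2 of 100 reaching the real count. Another labelling thus gave as many lists, so a structure among the arrays stays open for this count. The set layout of the controls stays open for both counts of genotype at control N. Of the 7 lists in shoot, 6 were lost with an estimated correlation (adjusted p = 0.279 for each). For lists in root, 71 of 100 labellings, the real one included, gave at least 1 list and 1 gave 5, so chance cannot be excluded.

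The 6 arrays of a genotype and tissue allow 10 splits, too few for a share under 0.05. The real and the highest other counts were 2058 and 0 in HD2967 root, 555 and 0 in K9107 root, 1219 and 32 in K307 root, 1246 and 2241 in CL root, 22 and 564 in HD2967 shoot, 64 and 286 in K9107 shoot, 28 and 4 in K307 shoot and 2057 and 32 in CL shoot. The number of splits reaching the real count was 1 in HD2967 root, 1 in K9107 root, 1 in K307 root, 2 in CL root, 2 in HD2967 shoot, 2 in K9107 shoot, 1 in K307 shoot and 1 in CL shoot. Where another split called more than the real one, it points to a structure of the arrays: in HD2967 shoots control 1 with stressed 1 and 2 stood against the rest, in K9107 shoots control 1 and 2 with stressed 3, and in CL roots control 1 and 3 with stressed 2.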
